A study of Mus musculus with 16 samples.

How the data were processed

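Total RNA from dorsal skin of 15-day mice of a mixed C57/BL6 and 129Ola background was hybridized to Illumina mouse expression bead arrays after Trizol and RNeasy extraction and biotin labelling of cRNA with a TotalPrep kit, per the labels. There were 16 arrays on 2 slides, 4 arrays for each of 4 groups, with 2 arrays of each group on each slide. The groups were control mice, mice with the floxed Shp2 gene and the Krox20-cre driver (Shp2lof), mice with a gain-of-function Mek1 allele and the same driver (Mek1gof), and mice with both alleles (Double). The position of an array on its slide went with its group, so position on the slide and group cannot be told apart. The labels do not say whether the 4 samples of a group came from separate animals.

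The deposited table of signals gives, for 25697 probes, the mean bead intensity on a linear scale, and beside it a deposited detection p_value (a p-value of the probe against the negative control beads of the same array). The submitters' processing notes name GenomeStudio, whose version is not given in the sources used here. The array medians differed and no value was near 0, so the deposited intensity values had neither been normalized between arrays nor, as far as the values show, background-subtracted. A second deposited table held the same intensity values rounded, with a largest difference of 0.05, and served as the unnormalized alternative.

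Signals were background-corrected and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3, which takes the background from the detection p-values, with an offset of 16, and were then on a log2 scale. The offset shrinks fold changes of genes near the background. A probe was kept when its detection p-value was below 0.05 on at least 4 arrays, which left 14631 probes (56.9% of all), and when the supplied gene table gave it exactly 1 gene symbol, which left 13765. Of all probes, 23978 had 1 symbol, 0 had several and 1719 had none, and 23962 were matched to the gene table by Entrez identifier. The 866 detected probes without a symbol were left out of the gene tests. Where several kept probes named the same gene, as for 2581 genes, the probe with the highest mean level over all 16 arrays stood for it, so 10232 genes were tested. No duplicate arrays were found.

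One linear model with a mean per group was fitted to all 16 arrays with limma (lmFit and eBayes, no covariate, 12 residual degrees of freedom and 5.74 from the prior), and the threshold was a Benjamini-Hochberg adjusted p of 0.05 over all genes tested. The comparisons were each mutant group against control, Double against each single mutant, and the factorial interaction, which is the Shp2lof effect with the Mek1gof allele minus the Shp2lof effect without it. Lists of genes for pathways, cell types and skin compartments (32 written, 29 with at least 5 measured members tested) were compared with all other genes by camera of limma with a preset correlation of 0.01, adjusted over the lists of a comparison. The list tests were repeated with an estimated correlation and with fry. Members past the threshold were counted over all genes tested and, a second time, adjusted over the list alone. How much of an effect the Double skin kept was measured as a slope through the origin, over the genes past the threshold in the single mutant, against a difference that shares no array with it.

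The groups, comparisons, tests, gene lists and the rule for naming genes were set before the data were examined. The rule named, for each mutant group against control, Ptpn11, Map2k1 and Egr2; the 10 largest increases and 10 largest decreases past the threshold for which every mutant array lay outside the control range; and up to 4 members past the threshold of each list past its test, or, where there was none, the 2 members with the smallest p, given as values. For the other comparisons it named the 5 largest increases and the 5 largest decreases past the threshold. Withheld or unnamed items were skipped. The alternatives were other normalizations and background offsets, the unnormalized signals, no detection filter and a stricter one, other ways to choose a probe, a fit of only the groups compared, array weights, slide and replicate number as blocks, each slide alone and each array left out in turn. Adding the Xist level or the skeletal muscle level as a covariate, leaving out 3 arrays with atypical levels of sex-linked genes, and choosing genes and effects on different arrays for the slopes were added after the data had been seen.

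The gene and list tests were run on 10232 genes simulated with the Shp2lof against control design. Of genes changed by 0.5, 1 and 2 on the log2 scale, 22.4%, 92.5% and 100% were recovered. Of 153 calls 10 were false (6.54%). Of 100 lists with no shift 5 had p below 0.05, but lists of genes that move together were not tried. The number of arrays limits the precision of every value. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.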

Results

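Gene expression was measured in dorsal skin of 15-day mice on 16 arrays, 4 each for control, Shp2lof, Mek1gof and Double skin. In Shp2lof the Krox20-cre driver acted on a floxed gene for Shp2 (Ptpn11), a tyrosine phosphatase that links receptors to the Ras and ERK pathway. In Mek1gof it acted on a gain-of-function allele of Mek1 (Map2k1), the kinase that phosphorylates ERK, and Double skin carried both. Between 13022 probes (Shp2lof 2) and 13959 probes (control 1) were detected per array, and the median signal per array lay between 71.33 and 95.88. Replicates 1 and 2 of each group were on slide 1, and replicates 3 and 4 on slide 2. Nothing states that the samples of a group were separate animals, so the p-values measure only the spread between these samples.

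The targeted genes and the gene of the Cre driver were read first. Ptpn11 had mean log2 levels of 12.87 ± 0.101 (SD, n = 4) in control, 12.82 ± 0.0655 in Shp2lof, 12.94 ± 0.147 in Mek1gof and 12.94 ± 0.141 in Double skin. Its single arrays read 12.96, 12.74, 12.83 and 12.94 in control, 12.84, 12.74, 12.81 and 12.90 in Shp2lof, 13.13, 12.84, 12.82 and 12.97 in Mek1gof, and 12.85, 12.91, 13.15 and 12.86 in Double. The Shp2lof minus control difference was -0.05 (adjusted p = 0.891, limma), and a pair of other detected Ptpn11 probes gave -0.17 (adjusted p = 0.57) and -0.26 (adjusted p = 0.44). Map2k1 was at 6.564 ± 0.538, 6.70 ± 0.282, 6.411 ± 0.383 and 6.597 ± 0.297 in control, Shp2lof, Mek1gof and Double (SD, n = 4). Its arrays read 6.262, 5.968, 6.904 and 7.119 in control, 6.349, 6.622, 7.008 and 6.822 in Shp2lof, 6.245, 5.948, 6.705 and 6.745 in Mek1gof, and 6.256, 6.444, 6.882 and 6.808 in Double. The Mek1gof minus control difference of Map2k1 was -0.15 (adjusted p = 0.913, limma). The probes' places relative to the altered exons are not given in the sources used here, and only part of the skin's cells use the driver, so these levels check neither genotype. Egr2 (Krox20), whose promoter drives the Cre, was at 10.22 ± 0.297, 9.74 ± 0.143, 9.962 ± 0.419 and 9.504 ± 0.281 in the same order. The Egr2 differences from control were -0.48 (adjusted p = 0.239), -0.26 (adjusted p = 0.736) and -0.72 (adjusted p = 0.0507) by limma. With slide as a block the last of these passed the threshold (adjusted p = 0.0442).

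Shp2lof against control asks what Shp2 loss with the driver does. Shp2lof skin had more transcript of the epidermal stress and wound response list and of single genes such as Stfa1, Pyy and Epgn, and less of the BMP and TGF-beta signalling list, of Krtap31-2 and of Hamp2. Stfa1, a cysteine protease inhibitor of the stefin family, rose 10.6-fold (log2 change 3.41 ± 0.46, SE, n = 4 against 4 arrays, adjusted p = 0.000356, limma). Pyy, the gut peptide hormone PYY, rose 8.77-fold (3.13 ± 0.24, adjusted p = 1.16e-06), and Epgn, a ligand of the EGF receptor, 4.13-fold (adjusted p = 0.000356). The cornified envelope genes Sprr2d, Sprr2g and Sprr2f rose 7.05-fold, 4.87-fold and 4.35-fold (adjusted p = 0.000502, 1.13e-05 and 0.00057), and the beta-defensin gene Defb4 4.08-fold (adjusted p = 0.000526). Sprr2d, Sprr2g, Mmp12, Defb4 and Ccl4 were detected on only 2 of 4 control arrays, so their folds start from the background. Chil1, a chitinase-like protein, Fcgr4, an Fc receptor of myeloid cells, and Mmp12, the macrophage metalloelastase, rose 5.48-fold, 5.48-fold and 4.7-fold (adjusted p = 2.58e-05, 7.33e-06 and 5.4e-05).

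The epidermal stress and wound response list shifted upward as a group in Shp2lof skin. Of its 25 measured members 11 rose, 1 fell and 13 did not pass (15 up and 2 down adjusted over the list alone). Its mean change was 0.97 (1.07 on slide 1, 0.88 on slide 2; camera adjusted p = 3.7e-10, and adjusted p = 0.044 with an estimated correlation). The 1 member that fell was Sprr2k, named after its value was seen (-0.75, adjusted p = 0.0251); Sprr2 and Stfa paralogs are so alike that their probes may bind each other's transcripts, which leaves single members uncertain. Interferon response genes were higher, with 3 of 15 members past the threshold and 12 not (4 adjusted over the list alone; mean 0.49, 0.48 and 0.50 on the slides, camera adjusted p = 1e-05, adjusted p = 0.13 with an estimated correlation). Among them Oasl2, an antiviral gene, rose 2.39-fold (1.26 ± 0.19, adjusted p = 0.00103), and the interferon-induced GTPase genes Igtp and Gbp2 changed by 1.26 (adjusted p = 0.0188) and 1.07 (adjusted p = 0.0387). Of 10 cytokine, chemokine and neutrophil genes 3 rose and 7 did not pass (4 adjusted over the list alone; mean 0.65 against a median of 0.29, camera adjusted p = 0.0078, adjusted p = 0.24 with an estimated correlation, and adjusted p = 0.12 on slide 2). These were the chemokine genes Cxcl1 (3.66-fold, adjusted p = 0.00475), Ccl7 (3.95-fold, adjusted p = 0.0268) and Ccl4 (2.63-fold, adjusted p = 0.0405). Cell cycle genes had a mean change of 0.48 (0.39 on slide 1, 0.56 on slide 2), with 2 of 32 past the threshold, 30 not, and 9 adjusted over the list alone. Their camera adjusted p was 7.1e-08, with adjusted p = 0.42 with an estimated correlation. The 2 members were the mitotic genes Plk1 (0.97 ± 0.25, adjusted p = 0.0445) and Prc1 (0.85 ± 0.19, adjusted p = 0.0241).

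The largest decreases in Shp2lof skin were those of Krtap31-2, Hamp2 and Krtap31-1, none of which belongs to a list. The hair keratin-associated protein genes Krtap31-2 and Krtap31-1, paralogs whose probes may bind each other's transcripts, fell 14.7-fold and 11.4-fold (log2 change -3.87 ± 0.41 and -3.51 ± 0.48, adjusted p = 4.35e-05 and 0.000356, limma, n = 4 against 4). Hamp2, which encodes a hepcidin, fell 12.8-fold (-3.67 ± 0.41, adjusted p = 5.12e-05). Cyp2g1, a cytochrome P450 gene, and the serpin genes Serpina3b and Serpinb6e fell 9.22-fold, 9.19-fold and 8.88-fold (adjusted p = 5.34e-05, 0.000466 and 0.000374). Aadacl4, Aldh3a1, an aldehyde dehydrogenase, and Ces1d, a carboxylesterase, fell 4.54-fold, 3.38-fold and 3.18-fold (adjusted p = 0.00235, 0.000861 and 0.0208). Of 9 sebaceous gland genes 2 fell and 7 did not pass (6 adjusted over the list alone; mean -0.91, -0.89 and -0.94 on the slides, camera adjusted p = 3.5e-07, adjusted p = 0.057 with an estimated correlation), the 2 being Cyp2g1 and Awat2, a wax ester synthase (3.79-fold, adjusted p = 0.0178). Of 28 fibroblast and extracellular matrix genes 4 fell and 24 did not pass (13 down and 1 up adjusted over the list alone; mean -0.41, -0.51 and -0.31 on the slides, camera adjusted p = 7.1e-08, adjusted p = 0.16 with an estimated correlation). They were the collagen I genes Col1a1 (2.2-fold, adjusted p = 0.0024) and Col1a2 (-1.07, adjusted p = 0.0286), Sparc (-0.66, adjusted p = 0.0248; its other probe read -1.12) and the elastin gene Eln (-0.63, adjusted p = 0.0188). Of 12 BMP and TGF-beta signalling genes 1 fell and 11 did not pass (6 adjusted over the list alone; mean -0.37, -0.40 and -0.33 on the slides, camera adjusted p = 0.00014, adjusted p = 0.028 with an estimated correlation). It was the growth factor gene Tgfb2 (-0.68 ± 0.16, adjusted p = 0.0309).

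Further lists were lower in Shp2lof skin by camera but not with an estimated correlation. Schwann cell and myelin genes had a mean of -0.43 (-0.34 and -0.53 on the slides, 1 of 13 past the threshold, 3 adjusted over the list alone, camera adjusted p = 1.1e-05, adjusted p = 0.16 with an estimated correlation). The 1 member was Fa2h, the fatty acid 2-hydroxylase of myelin and skin lipids, which fell 2.11-fold (-1.07 ± 0.22, adjusted p = 0.0128). Hair shaft genes had a mean of -0.28 (-0.15 and -0.41 on the slides, 1 of 34 past the threshold and also 1 adjusted over the list alone, camera adjusted p = 1e-05, adjusted p = 0.33 with an estimated correlation), with Krtap13-1 at -0.78 (adjusted p = 0.00901). Adipocyte genes (mean -0.31, -0.38 and -0.23 on the slides, 0 of 21 past the threshold, camera adjusted p = 0.00053, adjusted p = 0.27 with an estimated correlation) included Lipe at -0.56 (adjusted p = 0.0754) and Cidea at -1.05 (adjusted p = 0.127). Skeletal muscle genes (mean -0.29, -0.38 and -0.20 on the slides, 0 of 23 past the threshold, camera adjusted p = 0.0048, on slide 2 adjusted p = 0.088, adjusted p = 0.66 with an estimated correlation) included Myot at -0.81 (adjusted p = 0.0978) and Mylpf at -0.48 (adjusted p = 0.332). Inner root sheath genes (mean -0.22, -0.24 and -0.20 on the slides, 0 of 8 past the threshold, camera adjusted p = 0.038, on slide 2 adjusted p = 0.17, adjusted p = 0.55 with an estimated correlation) included Padi1 at -0.46 (adjusted p = 0.243) and Krt26 at -0.45 (adjusted p = 0.244). In each of these 3 lists limma had 0 members past the threshold adjusted over the list alone either, with 7, 1 and 4 members lower at an unadjusted p under 0.05. The inner root sheath call was lost without control 1, control 2 or Shp2lof 4 (adjusted p at most 0.16) and without 3 arrays of atypical sex-linked gene levels (adjusted p = 0.15).

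In total 261 genes passed the threshold in Shp2lof against control by limma, 154 higher and 107 lower (59% higher), of which 70 and 37 changed by more than 2-fold. With slide as a block 307 genes passed, on slide 1 alone 108 and on slide 2 alone 175. All 35 genes named here that passed did so with slide as a block. Their signs on the slides agreed, as without overlap they must. The control and Shp2lof arrays did not overlap for 254 of the 261 genes and for 11.5% of all genes, against 2.86% by chance. Without 1 array the count was 164 (control 2), 137 (control 3), 164 (Shp2lof 1), 130 (Shp2lof 2) and 154 (Shp2lof 4). With the skeletal muscle level as a covariate Ccl4, Ccl7, Gbp2 and Plk1 did not pass (adjusted p = 0.0762, 0.0529, 0.0715 and 0.0762). Their changes, 1.26, 1.82, 1.00 and 0.94, stayed about as large. Single arrays also decided Awat2 (without control 4, adjusted p = 0.06) and Eln (control 4 or Shp2lof 4, at most 0.0636). Ccl7, Igtp, Ces1d, Col1a2, Sparc, Prc1, Tgfb2, Gbp2, Ccl4 and Plk1 were each lost without any 1 of several arrays (adjusted p at most 0.0968, 0.0602, 0.0625, 0.0954, 0.0995, 0.0827, 0.103, 0.117, 0.139 and 0.139). In other planned settings Ccl4 was lost 4 times (adjusted p at most 0.0938, change as small as 0.77), and Ccl7, Col1a2 and Plk1 in 2 of them (at most 0.0761, 0.0685 and 0.143). Among 63 of the 261 genes with several probes, another probe had the opposite sign for 8, and for 16 all other probes passed too. Xist, a transcript of female cells, and the Y-linked Eif2s3y were both high in Shp2lof 4 (9.12 and 8.01). Without that array, Mek1gof 2 and Double 4, 138 genes passed. With the unnormalized signals 149 genes passed, 111 higher and 38 lower (74.5% higher).

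**Figure D1:**
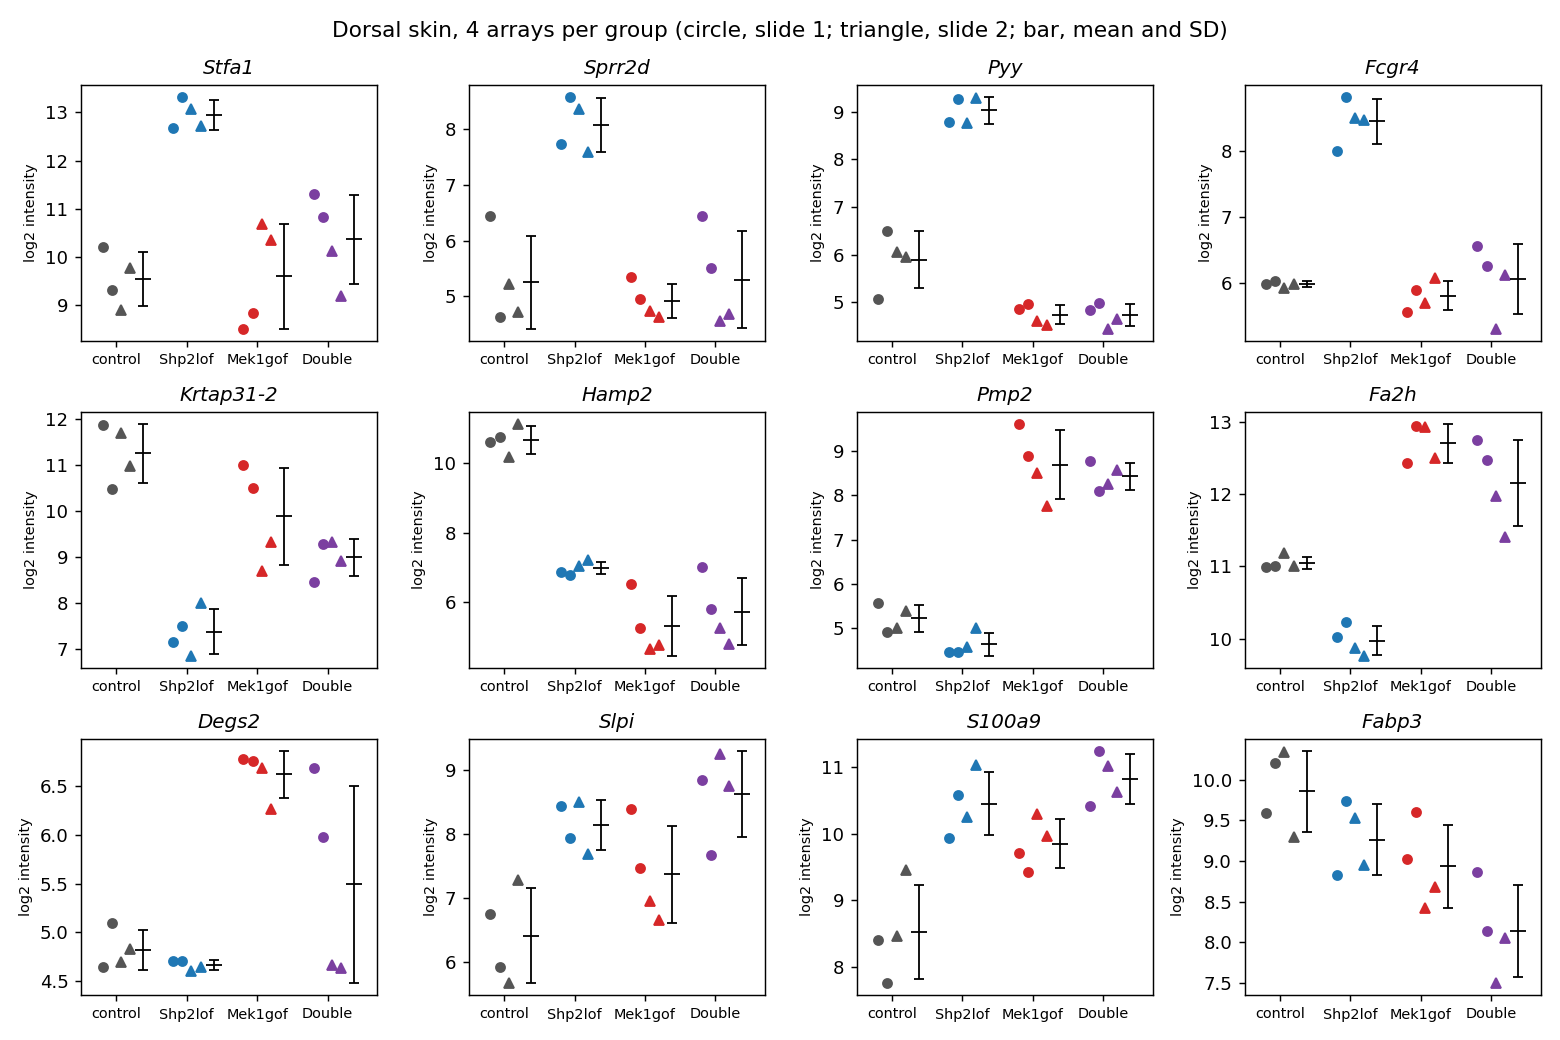
Normalized log2 level of 12 genes in each group, 1 point per array (circles, slide 1; triangles, slide 2), with mean and SD bars over 4 arrays per group.

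Mek1gof against control asks what the active Mek1 allele with the driver does. Mek1gof skin had more transcript of enzymes of cholesterol and fatty acid synthesis and of Pmp2, and less of Hamp2. Pmp2, the fatty acid-binding protein of peripheral myelin, rose 11-fold (log2 change 3.46 ± 0.28, SE, n = 4 against 4 arrays, adjusted p = 2.38e-06, limma; 4.00 on slide 1, 2.93 on slide 2). Fa2h rose 3.14-fold (1.65 ± 0.22, adjusted p = 0.00171), and Elovl3, a fatty acid elongase of sebocytes, 2.68-fold (1.42 ± 0.19, adjusted p = 0.00171). Acox2, a peroxisomal oxidase, and the sphingolipid enzyme genes Degs2 and Sgpp2 rose 3.02-fold, 3.5-fold and 4.6-fold (adjusted p = 0.00292, 0.0135 and 0.018). Degs2 and Sgpp2 were each detected on 1 of 4 control arrays, so their folds start from the background. Il13ra2, the decoy receptor of interleukin 13, rose 5.16-fold (2.37 ± 0.33, adjusted p = 0.00227), Tmem45b 3.8-fold (adjusted p = 0.00118), Clstn3 2.88-fold (adjusted p = 0.0135) and Ces4a, detected on 2 of 4 control arrays, 3.36-fold (adjusted p = 0.0135).

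Cholesterol synthesis genes rose as a group in Mek1gof skin, with 3 of 17 members past the threshold, 14 not, and 7 adjusted over the list alone. Their mean change was 0.44 (0.34 on slide 1, 0.55 on slide 2; camera adjusted p = 1.1e-09, adjusted p = 0.0055 with an estimated correlation). They were Hsd17b7 (2.09-fold, adjusted p = 0.0135), Mvd (1.84-fold, adjusted p = 0.00885) and Msmo1 (0.77 ± 0.17, adjusted p = 0.0468), 3 enzymes of the pathway. Fatty acid synthesis genes rose too, with 2 of 13 members past the threshold, 11 not, and 5 adjusted over the list alone (mean 0.34, 0.29 and 0.40 on the slides, camera adjusted p = 0.00013, adjusted p = 0.0086 with an estimated correlation). Acss2 and Acly, which make acetyl-CoA, changed by 0.88 (adjusted p = 0.0123) and 0.59 (adjusted p = 0.0326). Of 9 sebaceous gland genes 2 rose and 7 did not pass (3 adjusted over the list alone; mean 0.54, 0.63 and 0.45 on the slides, camera adjusted p = 0.00026, adjusted p = 0.19 with an estimated correlation), namely Elovl3 and the lipid droplet gene Plin2 (0.67, adjusted p = 0.0402). Schwann cell and myelin genes were higher on slide 1 (mean 0.66) and not on slide 2 (0.05, adjusted p = 0.95). Over both slides their mean was 0.35, with 1 of 13 past the threshold and also 1 adjusted over the list alone, Fa2h (camera adjusted p = 0.00088, adjusted p = 0.34 with an estimated correlation, and without Mek1gof 1 adjusted p = 0.088).

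Hamp2 fell 40.5-fold in Mek1gof skin (log2 change -5.34 ± 0.41, SE, n = 4 against 4, adjusted p = 1.38e-06, limma; -4.77 on slide 1, -5.92 on slide 2) and was detected on only 2 of the 4 Mek1gof arrays. Ppargc1a, the coactivator of mitochondrial genes, also detected on 2 of 4 Mek1gof arrays, fell 2.66-fold (-1.41 ± 0.22, adjusted p = 0.00714), and Serpina3b 4.31-fold (adjusted p = 0.0408). Aqp4, a water channel gene, and Ddx6, an RNA helicase gene, fell 2.87-fold and 2.86-fold (adjusted p = 0.0166 each). Rnf125 read -0.99 (adjusted p = 0.0106), but its other probes read -0.50 and 0.25, so its direction is uncertain. Ddr2, a collagen receptor gene, was detected on 0 of 4 Mek1gof arrays and was at least 1.63-fold lower (adjusted p = 0.0135). Pyy fell by 1.15 on the log2 scale (adjusted p = 0.0326), with detection on 1 of 4 Mek1gof arrays, and Cacna2d1, a calcium channel subunit gene, by 1.07 (adjusted p = 0.0374). Of 12 BMP and TGF-beta signalling genes 1 fell and 11 did not pass (2 adjusted over the list alone; mean -0.28, -0.34 and -0.21 on the slides, camera adjusted p = 0.00053, adjusted p = 0.064 on slide 2, adjusted p = 0.014 with an estimated correlation). It was Fst, which encodes the activin antagonist follistatin (-1.04 ± 0.22, adjusted p = 0.0408). Skeletal muscle genes had a mean of -0.65 (-0.29 on slide 1, -1.02 on slide 2), with 0 of 23 past the threshold by limma (9 lower at an unadjusted p under 0.05) and 1 adjusted over the list alone (camera adjusted p = 1.4e-12, adjusted p = 0.34 with an estimated correlation). Among them Mb read -1.28 (adjusted p = 0.0508, or 0.0387 with slide as a block) and Tcap -0.81 (adjusted p = 0.237). Extracellular matrix genes had a mean of -0.20 (-0.14 and -0.25 on the slides, 0 of 28 past the threshold by limma, 0 adjusted over the list alone, 4 lower at an unadjusted p under 0.05, camera adjusted p = 0.00053, adjusted p = 0.063 on slide 1, adjusted p = 0.49 with an estimated correlation), with Fbln2 at -0.55 (adjusted p = 0.168) and Col1a2 at -0.84 (adjusted p = 0.195).

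The 17 measured feedback and target genes of the ERK pathway did not shift in 1 direction in any mutant group by camera. By fry, tested for changes of either sign, they had adjusted p = 0.034, 0.0024 and 0.0038 in Shp2lof, Mek1gof and Double. Their median change was -0.06 in Shp2lof (camera adjusted p = 0.21), -0.06 in Mek1gof (adjusted p = 0.56, with a mean of 0.08 of the other sign) and -0.05 in Double skin (adjusted p = 0.54, with a mean of 0.01). Etv4, a transcription factor gene induced by ERK signalling and named after its values were seen, was past the threshold in Mek1gof (0.96, adjusted p = 0.0343) and read 0.65 in Double skin (adjusted p = 0.0744).

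In total 52 genes passed in Mek1gof against control by limma, 35 higher and 17 lower (67.3% higher), of which 15 and 8 changed by more than 2-fold. With slide as a block 84 genes passed, on slide 1 alone 28 and on slide 2 alone 193. All 26 named genes that passed did so with slide as a block. The groups did not overlap for each of the 52 genes and for 6.05% of all genes, against 2.86% by chance. With the skeletal muscle level as a covariate 13 genes passed. Of the named genes 16 were lost with it, including each named member of the cholesterol and fatty acid lists (adjusted p from 0.0763 to 0.3). Their changes stayed at a median of 0.87 of their size (0.66 for Aqp4 to 1.2 for Fst; Mvd read 0.84, Acss2 0.75 and Acly 0.52). The median SE of all genes grew 1.18-fold, so the losses do not show that muscle accounts for the changes. As lists, cholesterol and fatty acid synthesis still passed camera with it (adjusted p = 2.2e-06 and 0.0013). With the unnormalized signals 24 genes passed, 10 of them higher and 14 lower (41.7% higher). The unnormalized signals shifted the median of all genes by -0.118 in Mek1gof, -0.11 in Double and -0.147 in Double against Shp2lof. With them Mvd, Hsd17b7, Msmo1, Acss2 and Acly did not pass (adjusted p = 0.168, 0.0522, 0.225, 0.132 and 0.255). Without 1 array the count was 15 (control 2), 16 (control 3), 32 (Mek1gof 2), 31 (Mek1gof 3) and 19 (Mek1gof 4), and without the 3 arrays of atypical sex-linked gene levels it was 33. Pmp2, Il13ra2, Tmem45b, Fa2h, Acox2, Elovl3, Hamp2, Ppargc1a, Rnf125 and Mvd passed whichever array was left out, but Rnf125 did not with the mean of its probes (-0.415, adjusted p = 0.241). The others were lost without control 2 (Acss2, adjusted p = 0.0527), control 3 (Clstn3, 0.0531; Degs2, 0.0563), control 2 or 3 (Hsd17b7, at most 0.0581), or control 3 or Mek1gof 4 (Ddr2, at most 0.0549). Ces4a, Sgpp2, Aqp4, Ddx6, Acly, Pyy, Cacna2d1, Plin2, Serpina3b, Fst and Msmo1 were each lost without any 1 of several arrays (at most 0.0549, 0.0786, 0.0786, 0.0773, 0.114, 0.141, 0.148, 0.158, 0.111, 0.165 and 0.169). Other planned settings also ended calls. Pyy was lost in 7 of them (adjusted p from 0.0549 to 0.108), among them each other normalization, with a change as small as -0.61. Plin2 and Msmo1 were lost in 5 each (at most 0.501 and 0.225), and Serpina3b in 2 (at most 0.125). Among 11 of the 52 genes with several probes, another probe had the opposite sign for 2, and for 0 did all other probes pass too.

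Double against control asks what both alleles do. Double skin had more transcript of Pmp2, S100a9 and Bglap and less of Hamp2, Hbb-b2 and the BMP and TGF-beta signalling list. With an estimated correlation only that list of 9 passed. It was lower in Shp2lof (-0.37) and Mek1gof (-0.28) too, so it does not tell alleles or driver apart. Pmp2 rose 9.15-fold (log2 change 3.19 ± 0.28, SE, n = 4 against 4 arrays, adjusted p = 8.51e-06, limma). S100a9, a calprotectin subunit of inflamed epidermis and neutrophils, rose 4.91-fold (2.30 ± 0.30, adjusted p = 0.000763), and the protease inhibitor gene Slpi 4.65-fold (2.22 ± 0.39, adjusted p = 0.00647). The osteocalcin genes Bglap2 and Bglap, paralogs whose probes may bind each other's transcripts, rose 5.01-fold and 4.33-fold (adjusted p = 0.00242 and 0.000222), and a second Bglap probe read 1.10 (adjusted p = 0.012). The keratin gene Krt90, Il13ra2 and Apoc4, an apolipoprotein gene, rose 4.8-fold, 3.69-fold and 2.82-fold (adjusted p = 0.00295, 0.00628 and 0.033). Sprr2f rose 2.82-fold (adjusted p = 0.0122), Sprr2g, detected on 2 of 4 control arrays, by 1.34 on the log2 scale (adjusted p = 0.00351) and Cxcl1 2.82-fold (adjusted p = 0.0184). Of the 25 epidermal stress and wound response genes 4 rose and 21 did not pass (4 adjusted over the list alone; mean 0.47 against a median of 0.18, 0.65 on slide 1, 0.28 on slide 2 with adjusted p = 0.23). The camera adjusted p was 0.016, 0.48 with an estimated correlation and 0.12 without Double 1.

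Cell cycle genes were higher in Double skin, with 5 of 32 past the threshold, 27 not, and 11 adjusted over the list alone (mean 0.56, 0.34 on slide 1, 0.79 on slide 2, camera adjusted p = 4.9e-09, adjusted p = 0.48 with an estimated correlation). They included the replication genes Tk1 (1.04, adjusted p = 0.031), Mcm5 (0.92, adjusted p = 0.0221), Mcm2 (0.90, adjusted p = 0.0231) and Mcm4 (0.86, adjusted p = 0.017). Of 17 cholesterol synthesis genes 2 rose and 15 did not pass (4 adjusted over the list alone; mean 0.26, 0.23 on slide 1 with adjusted p = 0.22, 0.30 on slide 2, camera adjusted p = 0.028, adjusted p = 0.40 with an estimated correlation). The 2 were Hsd17b7 (0.99 ± 0.19, adjusted p = 0.00866) and Mvd (0.98 ± 0.14, adjusted p = 0.00203). The list call was lost without control 3, control 4 or Double 3 (adjusted p at most 0.1).

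Hamp2 fell 30.5-fold in Double skin (log2 change -4.93 ± 0.41, adjusted p = 4.98e-06, limma). Hbb-b2, an adult beta-globin gene, fell 18.9-fold (-4.24 ± 0.52, adjusted p = 0.000376) and was detected on only 1 of the 4 Double arrays. Serpinb6e fell 8.02-fold (adjusted p = 0.00203; -1.98 on slide 1, -4.02 on slide 2), Serpina3b 3.72-fold (adjusted p = 0.0245; -0.52 on slide 1, -3.27 on slide 2), Krtap31-1 4.92-fold (adjusted p = 0.0137) and Krtap31-2 4.79-fold (adjusted p = 0.00741). Aqp4 fell 4.36-fold (adjusted p = 0.000763) and Ces1d 2.95-fold (adjusted p = 0.0257). Pdk4, a kinase that restrains glucose oxidation, and Fabp3, the fatty acid-binding protein of heart and muscle, fell 3.7-fold and 3.28-fold (adjusted p = 0.0201 and 0.0068). Of 23 skeletal muscle genes 14 fell and 9 did not pass (21 adjusted over the list alone; mean -1.12, -1.65 on slide 1, -0.58 on slide 2, camera adjusted p = 9.8e-18, adjusted p = 0.31 with an estimated correlation). They included Myh4 (4.14-fold, adjusted p = 0.0201; -2.83 and -1.27 on the slides), Eno3 (-1.53, adjusted p = 0.011), Actn3 (-1.51, adjusted p = 0.0154) and Tnnt3 (-1.48, adjusted p = 0.0359; -2.49 and -0.46 on the slides), genes of fast muscle fibres. Of 12 BMP and TGF-beta signalling genes 2 fell and 10 did not pass (4 adjusted over the list alone; mean -0.39, -0.41 and -0.37 on the slides, camera adjusted p = 0.00021, adjusted p = 0.022 with an estimated correlation), namely Fst (-1.02, adjusted p = 0.0164) and Tgfb2 (-0.60, adjusted p = 0.0491).

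Hair and epidermal compartments were lower in Double skin by camera but not with an estimated correlation. Of 34 hair shaft genes 2 fell and 32 did not pass (4 adjusted over the list alone; mean -0.25, -0.34 and -0.17 on the slides, adjusted p = 0.076 on slide 2, camera adjusted p = 0.0049, adjusted p = 0.56 with an estimated correlation). They were Krtap1-4 (-1.48, adjusted p = 0.0201) and the hair desmoglein gene Dsg4 (-0.95, adjusted p = 0.0124). Inner root sheath genes had a mean of -0.28, but -0.66 on slide 1 and 0.09 on slide 2 (0 of 8 past the threshold, 2 adjusted over the list alone, camera adjusted p = 0.016, adjusted p = 0.48 with an estimated correlation), with Krt73 at -0.63 (adjusted p = 0.0696) and Krt72 at -0.52 (adjusted p = 0.0985). Outer root sheath and stem cell genes (mean -0.42, -0.27 on slide 1 with adjusted p = 0.13, -0.57 on slide 2, 0 of 10 past the threshold, 1 adjusted over the list alone, camera adjusted p = 0.016, adjusted p = 0.48 with an estimated correlation) included Barx2 at -0.98 (adjusted p = 0.0551) and Krt15 at -0.99 (adjusted p = 0.137). Basal epidermis genes (mean -0.36, -0.09 on slide 1 with adjusted p = 0.5, -0.62 on slide 2, 0 of 10 past the threshold, 0 adjusted over the list alone, camera adjusted p = 0.016, adjusted p = 0.48 with an estimated correlation) included Itga6 at -0.65 (adjusted p = 0.191) and Lamb3 at -0.61 (adjusted p = 0.233). At an unadjusted p under 0.05 limma had 2, 3 and 2 members lower in the inner root sheath, outer root sheath and basal lists. Single arrays decided the hair shaft list (without Double 2 adjusted p = 0.056), the inner root sheath list (Double 1 or 2, at most 0.1), the outer root sheath list (control 4 or Double 4, at most 0.09) and the basal epidermis list (control 4 or Double 4, at most 0.12).

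In total 397 genes passed in Double against control by limma, 188 higher and 209 lower (47.4% higher), of which 37 and 75 changed by more than 2-fold. With slide as a block 516 genes passed, on slide 1 alone 490 and on slide 2 alone 652. All 35 named genes that passed did so with slide as a block. The groups did not overlap for 356 of the 397 genes and for 12.5% of all genes, against 2.86% by chance. With the skeletal muscle level as a covariate 14 genes passed, among them Pmp2, Bglap, Krt90, Hamp2, Hbb-b2, Serpinb6e and Serpina3b. The other 28 genes named here did not (adjusted p from 0.116 for Slpi to 0.943 for Tnnt3). The muscle genes Tnnt3, Myh4, Actn3 and Eno3 fell to -0.10, -0.16, -0.20 and -0.29, and the Mcm genes, Hsd17b7 and Krtap31-1 to about 0.5 of their change. Slpi (2.56), Bglap2 (2.37), Apoc4 (1.72), Fst (-1.37) and Mvd (0.91) kept theirs. The median SE of all genes grew 1.45-fold. The cholesterol synthesis and epidermal stress lists did not pass with it either (camera adjusted p = 0.29 and 0.43). With the unnormalized signals 251 genes passed, 30 higher and 221 lower (12% higher). Without 1 array the count was 264 (control 1), 136 (control 2), 150 (control 3), 181 (Double 2) and 196 (Double 3). Single arrays also decided Krtap31-1 (without control 3, adjusted p = 0.0506), Cxcl1 (control 3 or Double 2, at most 0.0711), Fst (control 2 or Double 3, at most 0.0655), Actn3 (control 2 or 3, Double 2, at most 0.0595) and Pdk4 (control 2 or 3, Double 3, at most 0.0774). Mcm2, Mcm4, Mcm5 and Myh4 were each lost without control 2 or 3 or Double 2 or 3 (adjusted p at most 0.082, 0.0655, 0.0734 and 0.0763). Krtap1-4, Serpina3b, Ces1d, Apoc4, Tk1 and Tnnt3 were each lost without any 1 of several arrays (at most 0.0688, 0.0782, 0.0809, 0.0823, 0.0833 and 0.123). Tgfb2 was lost without any 1 of 12 arrays (at most 0.153), in 9 other planned settings (adjusted p from 0.0519 to 0.125, change as small as -0.34) and on each slide alone, so its call is weak. Cxcl1 was lost without background correction (0.86, adjusted p = 0.0576), with an offset of 50 (0.96, 0.0516) and with the unnormalized signals (0.75, 0.105). Myh4 and Tnnt3 were lost in 3 planned settings each (at most 0.0586 and 0.109). Of the 397 genes, 14 had another probe with the opposite sign, and 16 had other probes that all passed too.

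**Figure D2:**
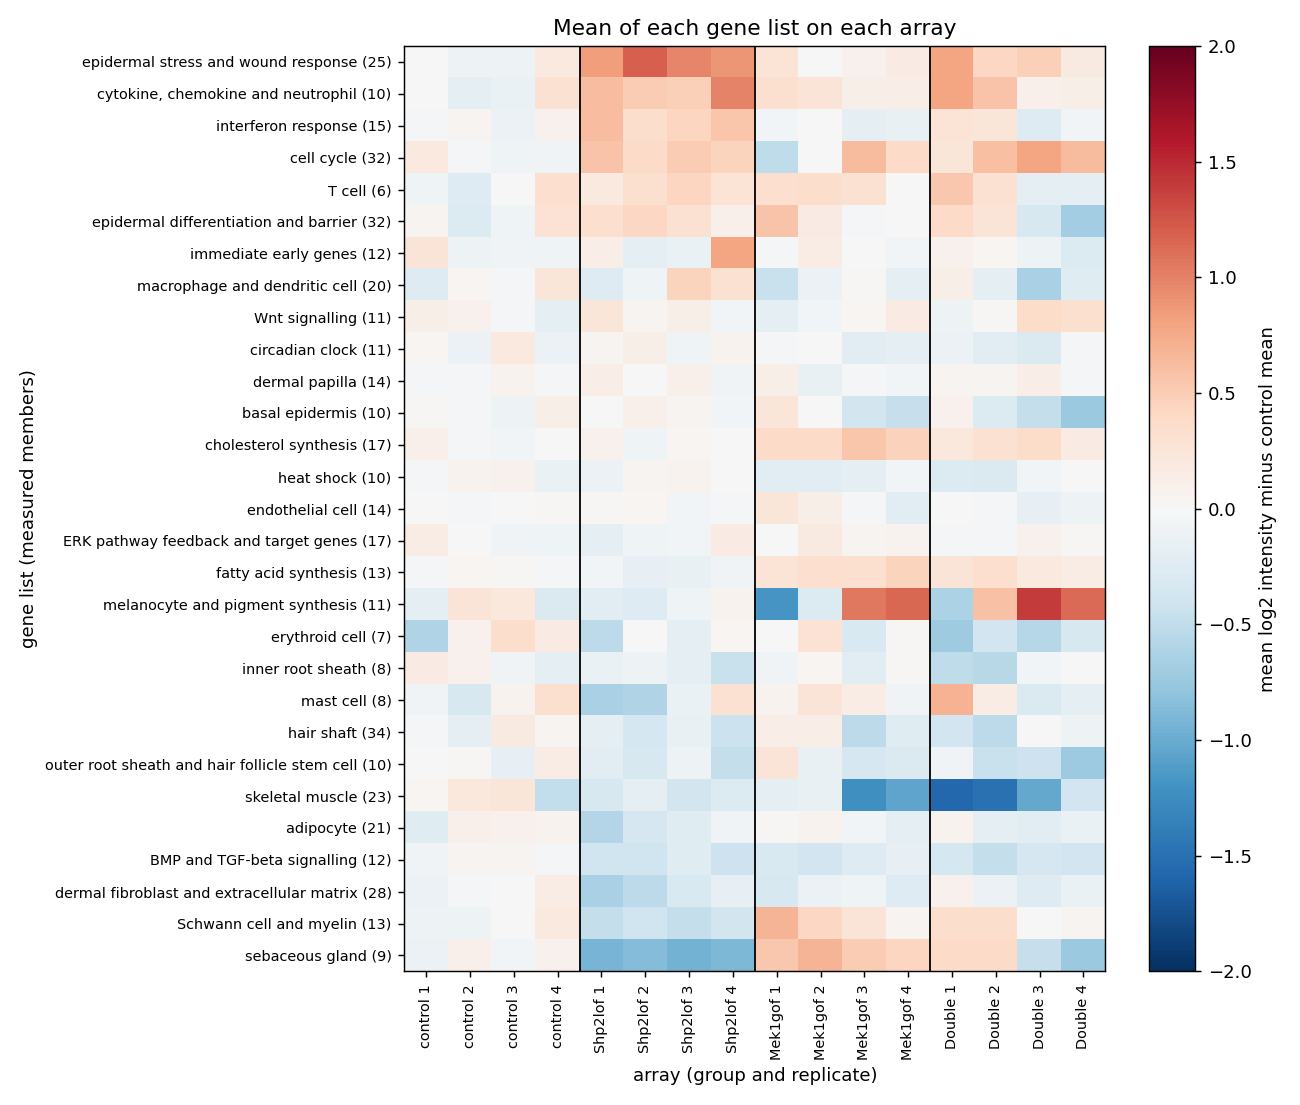
Mean log2 level of each of 29 gene lists on each of the 16 arrays, relative to the control mean, drawn as color.

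Muscle, pigment and sex-linked genes varied between arrays of a group. The muscle list averaged 0 ± 0.345 (SD, n = 4) in control, -0.29 ± 0.0798 in Shp2lof, -0.65 ± 0.569 in Mek1gof and -1.12 ± 0.545 in Double skin. Slide 2 minus slide 1 differences of the muscle list were -0.25, -0.07, -0.98 and 0.83 in the same order. Within a group, 2 genes differed between the slides in control, 3 in Shp2lof, 308 in Mek1gof and 781 in Double skin by limma. Melanocyte genes were higher on slide 2 by 1.83 in Mek1gof and 1.30 in Double, against -0.07 in control and 0.23 in Shp2lof (SE 0.42). The pigment enzyme gene Dct differed by 2.81 and 2.06, and Tyrp1 by 3.10 and 1.94, in Mek1gof and Double. Cell cycle genes differed by -0.17, 0.00498, 0.75 and 0.29 between the slides in control, Shp2lof, Mek1gof and Double. Xist was high in control 2 and 4, Shp2lof 4, Mek1gof 1 and 2, and Double 1 and 2, and lower in Double 4 (6.96), while Eif2s3y was also present in Mek1gof 2 (6.77).

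**Figure D3:**
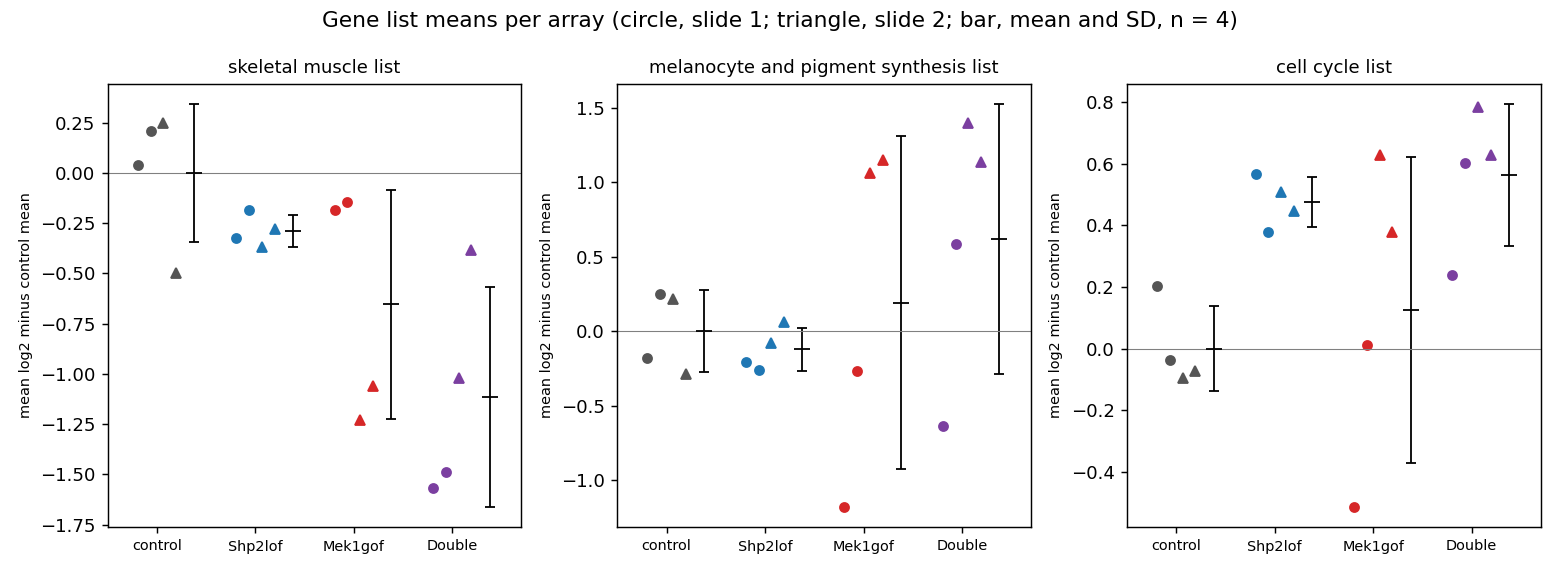
Mean log2 level of the skeletal muscle, melanocyte and cell cycle lists on each array, relative to the control mean, by group and slide.

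Double against Shp2lof gives the effect of the Mek1 allele where Shp2 is lost. Pmp2 was 13.7-fold higher in Double than in Shp2lof skin (log2 difference 3.78 ± 0.28, SE, n = 4 against 4, adjusted p = 5.79e-07, limma). Fa2h was 4.54-fold higher (adjusted p = 3.12e-05), Elovl6, a fatty acid elongase gene, 3.88-fold (adjusted p = 0.00205), Clstn3 3.54-fold (adjusted p = 0.00114) and Aadacl4 5.58-fold (adjusted p = 0.00114; 3.5 and 1.46 on the slides). Pyy was 19.7-fold lower (-4.30 ± 0.24, adjusted p = 6.13e-09), Hbb-b2 15.1-fold (adjusted p = 0.000613), Sprr2d 6.8-fold (adjusted p = 0.00114), Stfa1 6.03-fold (adjusted p = 0.00727) and Fcgr4 5.2-fold (adjusted p = 7.95e-06). Pmp2 was detected on 1 of 4 Shp2lof arrays, Pyy and Hbb-b2 on 1 of 4 Double arrays and Sprr2d on 2 of 4 Double arrays, so the folds of these 4 genes are bounded by the background. Elovl6 did not pass with the muscle level as a covariate (1.52, adjusted p = 0.0687). Genes of lipid and myelin lists were higher in Double skin. Of 13 Schwann cell and myelin genes 1 was past the threshold, with 7 adjusted over the list alone (mean 0.62, 0.80 and 0.45 on the slides, camera adjusted p = 2.3e-08, adjusted p = 0.075 with an estimated correlation). Of 9 sebaceous genes 3 were past it, with 6 adjusted over the list alone (mean 0.81, 1.29 and 0.33 on the slides, camera adjusted p = 1.7e-06, adjusted p = 0.075 with an estimated correlation). Of 13 fatty acid synthesis genes 3 were past it, with 6 adjusted over the list alone (mean 0.34, 0.41 and 0.27 on the slides, camera adjusted p = 0.00058, adjusted p = 0.052 with an estimated correlation). Of 17 cholesterol synthesis genes 1 was past it, with 4 adjusted over the list alone (mean 0.25, 0.26 and 0.25 on the slides, camera adjusted p = 0.0014, adjusted p = 0.11 with an estimated correlation).

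Stress and interferon genes were lower in Double than in Shp2lof skin. Of 25 epidermal stress genes 6 were lower and 1 higher (9 and 1 adjusted over the list alone; mean -0.51, -0.42 and -0.59 on the slides, camera adjusted p = 1.7e-05, adjusted p = 0.12 with an estimated correlation). Of 15 interferon genes 4 were lower (5 adjusted over the list alone; mean -0.44, -0.23 and -0.65 on the slides, camera adjusted p = 3.7e-05, adjusted p = 0.12 with an estimated correlation). Muscle genes were lower (mean -0.83, -1.28 and -0.38 on the slides, 0 past the threshold by limma, 19 at an unadjusted p under 0.05 and 19 adjusted over the list alone, camera adjusted p = 3.2e-14, adjusted p = 0.21 with an estimated correlation). Of the other lists past the camera test, extracellular matrix (0.30, 0.57 and 0.04 on the slides, adjusted p = 5.3e-05, on slide 2 adjusted p = 0.81), melanocyte (0.74, 0.21 and 1.28, adjusted p = 0.0014), mast cell (0.36, 1.05 and -0.32, adjusted p = 0.028) and adipocyte genes (0.19, 0.40 and -0.02, adjusted p = 0.035) were higher. With an estimated correlation these had adjusted p = 0.26, 0.42, 0.42 and 0.42. Basal epidermis (-0.38, -0.15 and -0.62 on the slides, adjusted p = 0.0014), epidermal differentiation (-0.38, -0.05 and -0.72, adjusted p = 9.9e-05), macrophage and dendritic cell (-0.35, 0.14 and -0.83, adjusted p = 0.0016), circadian clock (-0.21, -0.26 and -0.15, adjusted p = 0.028) and immediate early genes (-0.21, 0.09 and -0.52, adjusted p = 0.04) were lower. With an estimated correlation these had adjusted p = 0.26, 0.42, 0.42, 0.26 and 0.42. Of these 9 lists 1 extracellular matrix gene passed by limma and 0 members of the others. At an unadjusted p under 0.05, 1 melanocyte, 4 mast cell and 2 adipocyte genes were higher and 3 basal, 9 differentiation, 6 macrophage, 3 clock and 3 immediate early genes lower. Single arrays decided the adipocyte list (Shp2lof 1 or 2, Double 1 or 4, adjusted p at most 0.35), mast cell (Shp2lof 1 or 2, Double 1, at most 0.37), clock (Shp2lof 2 or 4, Double 2 or 3, at most 0.1), immediate early (Shp2lof 4, Double 3 or 4, at most 0.75), epidermal differentiation (Double 4, 0.057) and macrophage list (Shp2lof 3, 0.062). In total 99 genes passed in Double against Shp2lof by limma, 44 higher and 55 lower (44.4% higher), with 158 with slide as a block, 290 on slide 1 alone and 277 on slide 2 alone. Without Shp2lof 3 the count was 56, with the muscle level as a covariate 51, and with the unnormalized signals 178, 14 higher and 164 lower (7.87% higher). All 10 named genes had the same sign on each slide and passed whichever array was left out.

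Double against Mek1gof gives the effect of Shp2 loss where the Mek1 allele is active. Sprr2g, detected on 0 of 4 Mek1gof arrays, was at least 2.61-fold higher in Double skin (adjusted p = 0.00123, limma, n = 4 against 4), and passed whichever array was left out. Spink8, a serine protease inhibitor gene, was 3.73-fold higher (log2 difference 1.90 ± 0.31, SE, adjusted p = 0.0135), Bglap2 3.58-fold (adjusted p = 0.0289), Clic6 3.5-fold (adjusted p = 0.0401) and Sprr2f 2.96-fold (adjusted p = 0.0331). Fabp9 was 2.24-fold lower (adjusted p = 0.00941), Upp1, a uridine phosphorylase gene, 2.57-fold (adjusted p = 0.028), Dio3, a deiodinase gene detected on 2 of 4 Double arrays, 2.47-fold (adjusted p = 0.028), Fam167a 2.19-fold (adjusted p = 0.028) and Tesc 1.99-fold (adjusted p = 0.0331). Of 25 epidermal stress genes 2, Sprr2f and Sprr2g, were higher (4 up and 1 down adjusted over the list alone; mean 0.34, 0.47 and 0.20 on the slides, camera adjusted p = 0.015, adjusted p = 0.5 with an estimated correlation). Cell cycle genes (mean 0.44, 0.67 and 0.20 on the slides, 0 of 32 past the threshold by limma, 12 at an unadjusted p under 0.05, 1 adjusted over the list alone, camera adjusted p = 1.5e-08) were higher, with adjusted p = 0.5 with an estimated correlation. Their mean was 0.224 without Mek1gof 1, which alone read -0.512. Of 9 sebaceous genes 1, Plin2, named after its value was seen, was lower (-0.69, adjusted p = 0.0439; 2 adjusted over the list alone, list mean -0.65, -0.23 and -1.07 on the slides, camera adjusted p = 1.8e-06, adjusted p = 0.21 with an estimated correlation). Muscle (-0.46, adjusted p = 2.4e-06) passed in opposite directions on the slides (-1.37, adjusted p = 1.2e-30, and 0.44, adjusted p = 3.2e-05), so it has no common direction. Epidermal differentiation (-0.26, -0.04 and -0.49, adjusted p = 0.0029), cholesterol synthesis (-0.18, -0.12 and -0.24, adjusted p = 0.0061), inner root sheath (-0.22, -0.52 and 0.07, adjusted p = 0.016) and erythroid genes (-0.50, -0.69 and -0.30, adjusted p = 0.021, but a mean of -0.17 without Hbb-b2 at -2.43) were lower by camera. With an estimated correlation these 5 lists had adjusted p = 0.5, 0.53, 0.3, 0.5 and 0.5. By limma 0 of their members passed, and 8, 2, 4, 2 and 2 were lower at an unadjusted p under 0.05. Single arrays decided the epidermal differentiation (Mek1gof 1 or Double 4, adjusted p at most 0.34), stress (Double 1, 0.18), erythroid (Mek1gof 2 or Double 1, at most 0.13) and inner root sheath lists (Double 1 or 2, at most 0.18), and 13 or 14 lists passed without Mek1gof 3 or 4 against 8 with all arrays. In total 29 genes passed in Double against Mek1gof by limma, 18 higher and 11 lower (62.1% higher), with 37 with slide as a block, 192 on slide 1 alone and 76 on slide 2 alone. Parting these 8 arrays by slide instead gave 641 genes. With the muscle level as a covariate Bglap2, Clic6, Dio3, Fam167a, Sprr2f, Tesc and Upp1 did not pass (adjusted p from 0.0739 to 0.131). They kept a median of 0.94 of their change (lowest 0.86). The count was 8 (without Mek1gof 1), 5 (Mek1gof 2), 15 (Double 2), 10 (Double 3), 13 (Double 4), 15 with the muscle level as a covariate, 4 with the unnormalized signals (3 higher and 1 lower, 75% higher) and 1 without the 3 arrays of atypical sex-linked gene levels. Fabp9 and Spink8 were lost without Mek1gof 2 (adjusted p = 0.053 and 0.0823), and Dio3, Bglap2, Fam167a and Upp1 without any 1 of several arrays (at most 0.125, 0.134, 0.133 and 0.134). Sprr2f, Tesc and Clic6 were lost in the same way (at most 0.155, 0.133 and 0.148), and in 7, 7 and 6 other planned settings (at most 0.263, 0.338 and 0.358). Bglap2, Dio3 and Fam167a were lost in 3 (at most 0.313, 0.188 and 0.264).

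The interaction asks whether the Shp2lof effect differed with the Mek1 allele. Whether control mice had the driver is not stated. If not, a driver effect enters each comparison with control and, reversed, the interaction. Pyy, Fcgr4, Serpinb3a (a serpin of inflamed epidermis), Foxp3 (of regulatory T cells) and Slc2a1 (glucose transporter GLUT1) rose in Shp2lof skin. Shp2 loss had a lower effect on each where the Mek1 allele was active. The interaction estimate was -3.14 ± 0.33 for Pyy (SE, n = 4 per group, adjusted p = 0.000246, limma). Fcgr4 had -2.21 ± 0.31, Serpinb3a -1.80 ± 0.25 and Foxp3 -1.62 ± 0.22 (adjusted p = 0.00273 each). Slc2a1 had -1.53 ± 0.23 (adjusted p = 0.00661). Slc2a1 averaged 8.94, 10.24, 9.13 and 8.90 and Foxp3 5.01, 6.58, 5.58 and 5.52 in control, Shp2lof, Mek1gof and Double; a second Foxp3 probe read 0.57 in Shp2lof (adjusted p = 0.058). Serpinb3a was detected on 0 of 4 control arrays, and Serpinb3 paralogs are alike, so it is uncertain. The interferon-induced genes Irf1 (-1.25, adjusted p = 0.0101) and Tap2 (-1.26, adjusted p = 0.0221), named after their values were seen, moved in the same direction, but another Irf1 probe had the opposite sign in Shp2lof skin. Hamp2 had an estimate of 4.08 ± 0.57 (adjusted p = 0.00273), with means of 10.66, 6.99, 5.32 and 5.73. Additive effects would put Double at 1.64, below the lowest array level (4.27), so the background sets at least 2.63 of the estimate. The rest was not tested. Pyy and Serpinb3a were each detected on 1 of 4 Mek1gof and 1 of 4 Double arrays, so the background bounds their estimates too. Serpina3b had 3.41 ± 0.63 (adjusted p = 0.0499), of which the background sets at least 0.80 (additive level 3.47), and was lost in 4 other planned settings (at most 0.148). In total 9 genes passed, 2 higher and 7 lower, against 17 with slide as a block, 8 on slide 1 alone and 36 on slide 2 alone. Without the 3 arrays of atypical sex-linked gene levels Fcgr4 and Slc2a1 did not pass (adjusted p = 0.0527 and 0.118), and Foxp3 did not with the unnormalized signals (-0.95, 0.0912) or the mean of its probes (-0.98, 0.0971). Without Double 1 or Double 2 the count was 19 or 16. Serpina3b was lost without any 1 of several arrays (adjusted p at most 0.152), while the other 6 genes named by the rule passed whichever array was left out. Of 29 lists 12 passed camera, 6 higher and 6 lower, and by camera 0 of them with an estimated correlation (3 lists at an unadjusted p under 0.05) and 0 by fry, the lowest being adjusted p = 0.17 with an estimated correlation for extracellular matrix (mean 0.50), BMP and TGF-beta signalling (mean 0.25) and epidermal stress genes (mean -0.64).

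Gene sets were then compared across the mutants. Of the genes past the threshold, 47 were higher and 44 lower in both Shp2lof and Double skin, with 2.8 and 2.2 expected by chance, and 2 went opposite ways. Mek1gof and Double skin shared 25 higher and 15 lower genes (0.64 and 0.35 expected) and 0 opposite ones. Shp2lof and Mek1gof shared 2 higher and 7 lower genes (0.53 and 0.18 expected), with 2 opposite. These pairs use the same control arrays, which alone give correlations across genes near 0.5 (0.5, 0.499 and 0.498 on data simulated without effects) against 0.593, 0.68 and 0.424 measured. With the controls split the correlations were 0.405, 0.438 and 0.208, and the shared genes 10, 3 and 1.25. Differences sharing no array gave how much of each effect Double kept. Over the 261 Shp2lof genes the slope of Double minus Mek1gof on Shp2lof minus control was 0.289, with the same sign in 214 (82%) and 18 past the threshold in both (0.25 to 0.285 when genes and effects came from different arrays, over 8 to 32 genes, 0.176 on slide 2). Over the 52 Mek1gof genes the slope of Double minus Shp2lof on Mek1gof minus control was 0.577, with the same sign in 50 (96.2%) and 16 past the threshold in both (0.547 to 0.91 in the same way, over 2 to 5 genes, 0.389 on slide 2, 0.424 unnormalized). Hamp2 (0.41 for -3.67, -1.26 for -5.34), bounded by the background, lowers both slopes, and Pyy raises the second. Genes are not independent, and whether the slopes differ was not tested.

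**Figure D4:**
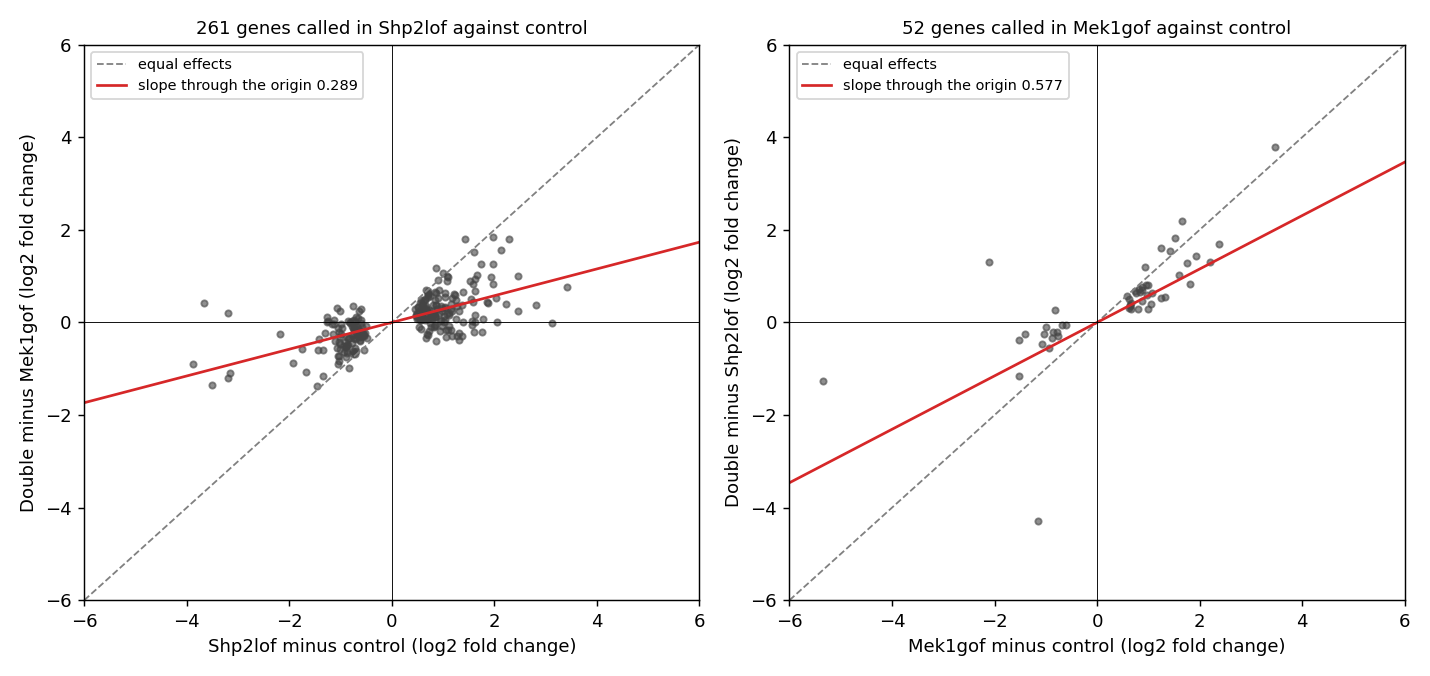
Log2 change of each gene past the threshold in a single mutant (x axis, single mutant minus control) against the log2 difference that the same allele made on the other mutant background (y axis), 1 point per gene, with the fitted slope through the origin.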

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

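The tests of the melanocyte pattern, of macrophage and dendritic cell genes and of the globin genes were chosen only after their results had been seen, while the Xist covariate, the fit without 3 arrays of atypical sex-linked gene levels, the count over splits balanced by slide and the regrouping of residuals, which replaced a test whose result was known, were added after the data had been seen.

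Melanocyte and pigment genes were higher on slide 2 than on slide 1 in Mek1gof and Double skin only, with 1.83 and 1.30 (SE 0.42) against -0.07 in control and 0.23 in Shp2lof. An effect of the hybridization slide as such would shift every group, but control and Shp2lof shifted by 0.049 (SE 0.19) of the shift of the others, which argues against it, as the -0.017 (SE 0.17) of the Mek1gof shift that the Xist level accounts for does against a sex effect shared by all groups; 1 limited to Mek1gof and Double stays open, as sex goes with slide in Mek1gof (Xist 9.29 and 8.82 against 5.02 and 5.77) and their own slope gives -0.22 (SE 0.94). A candidate explanation is a different stage of the hair cycle, since over 16 arrays the melanocyte and cell cycle lists, as deviations from group means, correlated with r = 0.86 (permutation p = 0.0087, adjusted p = 0.014 over 8 relations; Spearman rho = 0.747, permutation p = 0.038; r = 0.782 without the 2 farthest arrays; 0.631 within slides). That relation was absent from the control and Shp2lof arrays (r = -0.296) and present in Mek1gof and Double arrays (r = 0.938), and the hair shaft (r = -0.251, permutation p = 0.52) and inner root sheath lists (0.291, 0.42) did not follow the melanocyte list, which leaves it open; a first version of the test, which did not ask for the relation in control and Shp2lof, had been met. A slide effect limited to the chip positions of Mek1gof and Double, and a different tissue composition, stay open too (the basal epidermis list correlated with the melanocyte list at r = -0.936, permutation p = 0.0011, adjusted p = 0.0044, rho = -0.932, permutation p = 0.00045, r = -0.967 without the 2 farthest arrays), and an effect of the Mek1 allele that differed between the samples of the slides was not tested.

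The interaction passed for 9 genes, with estimates of -3.14 for Pyy, -2.21 for Fcgr4, -1.80 for Serpinb3a, -1.62 for Foxp3, -1.53 for Slc2a1, -1.26 for Tap2, -1.25 for Irf1, 4.08 for Hamp2 and 3.41 for Serpina3b. The background sets at least 2.63 (Hamp2) and 0.80 (Serpina3b) of these, and a driver effect was not tested. For the immune and epidermal genes, higher in Shp2lof than in Double skin, a different share of females and males is argued against by a median ratio of the 9 estimates of 1.02 (also 1.02 over the 7 negative ones) with the Xist level as a covariate, where 9 of 9 still passed; an earlier version of the sex test for the melanocyte pattern, which split arrays by Xist, was replaced. Leaving out the 3 arrays of atypical sex-linked gene levels gave a median ratio of 0.993 (0.99 over the 7), which argues against these arrays as the source, although 5 of 9 genes still passed and Fcgr4 (-2.19 ± 0.37, adjusted p = 0.053), Irf1 (-1.11 ± 0.23, 0.16), Slc2a1 (-1.52 ± 0.28, 0.12) and Tap2 (-1.26 ± 0.24, 0.13) did not, with SEs of 0.31, 0.20, 0.23 and 0.22 on all arrays. A rise shared by 20 macrophage and dendritic cell markers is argued against by their Shp2lof median of 0.046 (SD 0.36, 11 above 0). Of them Aif1 rose (1.01, adjusted p = 0.0085). Rises of some such cells, or of others, stay open. In Shp2lof the T cell list had a mean of 0.301 (camera adjusted p = 0.077) and the mast cell list -0.272 (0.11). The T cell interaction was -0.432 (adjusted p = 0.03, or 0.5 with an estimated correlation). An effect of the alleles was not tested.

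Hbb-b2 lay between 4.54 and 5.11 on the 4 Double arrays, near the background. Fewer red blood cells would lower the other erythroid genes as far, but their median in Double against control was -0.39 (SD 0.52, 5 genes, from -0.766 to 0.42), against -4.24 for Hbb-b2, which argues against it. A candidate explanation is a beta-globin haplotype segregating in the mixed strain, where Hbb-b2 and Hbb-bt would mirror each other. Their deviations from group means correlated with r = -0.22 (permutation p = 0.32), which cannot show a haplotype fixed in a group and leaves it open. The pooled r of -0.605, which had met a first version of the test, mixes in the group difference. Hbb-bt was 8.69 to 9.89 in Double (1.83 against control, adjusted p = 0.14). Hbb-b2 was also low in Mek1gof 1 and 3 (6.2 and 5.68; Hbb-bt 9.38 and 9.72), but both were high in control 3 and 4. An effect of both alleles together was not tested.

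Of 29 lists 12 had a different Shp2lof effect with the Mek1 allele by camera with the preset correlation, but 0 of them with an estimated correlation and 0 by fry. Their mean differences were 0.226 (adipocyte), 0.253 (BMP and TGF-beta signalling), -0.189 (cholesterol synthesis), -0.464 (cytokine), 0.497 (extracellular matrix), -0.557 (epidermal differentiation), -0.636 (epidermal stress), 0.151 (hair shaft, with -0.431 on slide 1 and 0.732 on slide 2), -0.342 (interferon), 0.551 (melanocyte), 0.268 (Schwann cell) and -0.432 (T cell).

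Single arrays lay far from the other 3 of their group in 21 of 556 groups examined, where chance gives about 1 in 20, or 28. The number given is the gap to the nearest array as a share of the range of the group. In control the distant array was control 2 for Defb4 (0.846) and Tgfb2 (0.878), control 4 for Eln (0.896) and Myot (0.865), control 3 for Fa2h (0.877) and the dermal papilla list (0.938), and control 1 for the adipocyte (0.9) and immediate early lists (0.898). In Shp2lof it was Shp2lof 2 for Defb4 (0.951) and for the number of probes detected (0.839), Shp2lof 3 for Plin2 (0.841) and the BMP and TGF-beta signalling list (0.956), and Shp2lof 4 for Tesc (0.901). In Mek1gof it was Mek1gof 2 for Ccl7 (0.845), Mek1gof 3 for Padi1 (0.838) and Acss2 (0.893), Mek1gof 1 for Acly (0.919), and Mek1gof 4 for the T cell list (0.859). In Double it was Double 2 for Mmp12 (0.871), Double 4 for Plin2 (0.896) and Double 1 for Bglap (0.852).

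Other groupings of the same arrays were fitted in the same way. For 4 comparisons only the real split of 35 gave as many genes. These were Shp2lof against control (261, highest other 1), Mek1gof against control (52, highest other 2), Double against control (397, highest other 30) and Double against Shp2lof (99, highest other 2). For the interaction a first count (3 of 100 regroupings with at least 9 genes, highest other 18) decides nothing, as single-allele effects stay in the residual. With these removed and the residuals regrouped within slides 2 of 100, the real one included, gave at least 9 (highest other 24). This assumes groups of equal spread, so chance stays open. For Double against Mek1gof 2 of 35 gave at least 29 genes, the real one and the one that follows the slides, which gave 641 and points to a structure of these samples by slide. The 18 splits of each comparison that part each slide equally, as the groups do, are too few for a share under 0.05, so they exclude chance in no comparison. The highest others were 1, 0, 30 and 0 in the 4 comparisons above and 18 here. In Double against Mek1gof with slide as a block 37 genes passed, and within the slides 192 and 76.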

How the results depend on the processing

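The Xist and muscle covariates, the set without 3 arrays of atypical sex-linked gene levels and the choice of genes and effects on different arrays were tried only after the data had been seen. Of the results for named genes under all alternatives 4628 kept their direction and their side of the threshold, 566 lost the call, 55 gained one and 18 reversed, all of the last among Ptpn11, Map2k1 and Egr2, which passed in no comparison as reported; of those for lists 2004 kept both, 270 lost the call and 11 reversed. The counts of genes that moved by over 1.5 times are given in the order of the settings. Where fewer arrays, genes or groups enter, power differs by construction, and otherwise the cause was not tested. With the unnormalized signals 149 genes passed in Shp2lof against control, 24 in Mek1gof against control, 251 in Double against control, 178 in Double against Shp2lof and 4 in Double against Mek1gof. Without a detection filter (16593 genes) 34 passed in Mek1gof against control and 11 in Double against Mek1gof, and with detection on all 16 arrays (7368 genes) 59 in Double against Shp2lof, 8 in Double against Mek1gof and 3 in the interaction of Shp2lof and Mek1gof. With slide as a block these were 84 (Mek1gof against control), 158 (Double against Shp2lof) and 17 (interaction). On slide 1 alone they were 108 (Shp2lof), 28 (Mek1gof), 290 (Double against Shp2lof) and 192 (Double against Mek1gof), and on slide 2 alone 193 (Mek1gof), 652 (Double), 277 (Double against Shp2lof), 76 (Double against Mek1gof) and 36 (interaction). Fitting only the groups compared gave 408 (Shp2lof), 257 (Double) and 3 (Double against Mek1gof), and array weights 463 (Shp2lof), 115 (Mek1gof), 150 (Double against Shp2lof) and 17 (interaction). The muscle covariate gave 13 (Mek1gof), 14 (Double), 51 (Double against Shp2lof) and 15 (Double against Mek1gof), the Xist covariate 14 (interaction), and leaving out the 3 arrays 138 (Shp2lof), 33 (Mek1gof), 1 (Double against Mek1gof) and 5 (interaction). Without 1 array the counts ranged from 130 to 294 (Shp2lof), 15 to 73 (Mek1gof), 136 to 492 (Double), 56 to 135 (Double against Shp2lof), 5 to 36 (Double against Mek1gof) and 7 to 19 (interaction).

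Of 12, 7, 9, 16, 8 and 12 lists past camera in Shp2lof, Mek1gof, Double, Double against Shp2lof, Double against Mek1gof and the interaction, 2, 3, 1, 0, 0 and 0 passed with an estimated correlation, which allows more for genes that move together, and 7, 4, 4, 6, 0 and 0 with fry. The number of lists was also 12 (unnormalized) and 13 on each slide alone in Mek1gof, 14 on slide 2 in Double, 10 on slide 1 in Double against Shp2lof, 5 without a filter and 4 with the muscle covariate in Double against Mek1gof, and 7 with detection on all arrays in the interaction. Without 1 array it ranged from 11 to 14, 7 to 11, 6 to 13, 13 to 17, 7 to 14 and 6 to 12. The share of the Mek1gof changes kept was 0.424 (unnormalized), 0.389 (slide 2) and 0.726 (genes and effects from different arrays, 2 to 5 genes at a time), and 0.49 to 0.649 without 1 array. The share of the Shp2lof changes kept was 0.176 (slide 2), 0.224 (without the 3 arrays) and 0.398 (split controls, with Double minus control), and 0.254 to 0.306 without 1 array. Lists that reversed were adipocyte (-0.0247, slide 2), mast cell (-0.321, slide 2), macrophage (0.139, slide 1) and immediate early genes (0.0939, slide 1; 0.072, without the 3 arrays) in Double against Shp2lof, muscle (0.44) and inner root sheath (0.0719) in Double against Mek1gof on slide 2, the inner root sheath list in Double against control (0.091, slide 2; 0.0366, muscle covariate), and hair shaft in Double (0.127, muscle covariate) and in the interaction (-0.431, slide 1). Reversed levels were Egr2 in Mek1gof (0.259, slide 1), Ptpn11 in Double against control (-0.000773, cyclic loess; -0.116, unnormalized; -0.0735, mean of probes) and in Mek1gof (-0.126, unnormalized). Map2k1 in Double against control reversed (-0.135, unnormalized; -0.167, slide 2; -0.252, muscle covariate; -0.0364, without the 3 arrays; -0.0666, -0.165, -0.0609 and -0.0364 without control 1, control 2, Double 3 and Double 4, of a range of -0.165 to 0.219), in Mek1gof (0.00137, without the 3 arrays; 0.0322 without control 4 and 0.00137 without Mek1gof 2, of a range of -0.351 to 0.0322) and in Shp2lof (-0.0968, slide 2; -0.0618 without control 2, of a range of -0.0618 to 0.322). Replicate numbers were not taken to pair the samples, as only 9 of 24 pairs of equal number had r above 0.1 (-0.229 to 0.384), although 10 of 16 arrays correlated best with an array of their own number, a hint from the data and not from the design. With them as a block Msmo1 (adjusted p = 0.0681) and Plin2 (0.0551) in Mek1gof, Sprr2f (0.0623) and Tesc (0.0547) in Double against Mek1gof and Serpina3b (0.0645) in the interaction were lost. Counts with it were 284 (Shp2lof against control), 85 (Mek1gof), 464 (Double), 131 (Double against Shp2lof), 27 (Double against Mek1gof) and 10 (interaction). Signals near the background limit the folds of dim genes.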

Other observations

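The genes below were chosen after their values had been seen, and the test of the region around Ptpn11 was chosen only after the result had been seen. They are single genes outside the naming rule in the comparisons given, and no list that passed stands behind them. Shh, the sonic hedgehog ligand gene of the hair follicle, was higher in Shp2lof skin (log2 change 1.53, adjusted p = 4.35e-05, limma) and in Double skin (1.06, adjusted p = 0.0032), and read 0.17 in Mek1gof skin (adjusted p = 0.807); Double exceeded Mek1gof by 0.89 (adjusted p = 0.028). The 3 measured members of the hedgehog list were too few to test and had medians of 0.28, 0.17 and 0.21 in Shp2lof, Mek1gof and Double. Of Wnt signalling genes, Nkd2, an inhibitor of the pathway, read 0.58 (adjusted p = 0.0355) and Wnt5a -0.59 (adjusted p = 0.0268) in Shp2lof, and Sp5, a target of the pathway, 0.83 in Double skin (adjusted p = 0.0147), each past the threshold. The Wnt list did not pass camera (adjusted p = 0.78 in Shp2lof, 0.96 in Mek1gof and 0.29 in Double). Bglap, among the largest increases of Double skin, read 1.97 in Shp2lof skin as well (adjusted p = 0.000208).

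Several lists did not pass their test in any comparison with control. The median changes in Shp2lof, Mek1gof and Double were -0.01, 0.06 and -0.02 for endothelial genes, 0.05, -0.20 and -0.20 for macrophage and dendritic cell genes, 0.29, 0.23 and 0.12 for T cell genes, -0.32, 0.12 and -0.02 for mast cell genes, and 0.11, 0.04 and -0.19 for epidermal differentiation genes.

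A region of the genome carried along with the floxed Ptpn11 allele from another strain could add differences among the neighbours of Ptpn11 in Shp2lof skin. Of the 200 tested genes nearest to Ptpn11, 8 passed in Shp2lof against control, compared with 253 of the 10032 others, an odds ratio of 1.61 (95% interval 0.678 to 3.29; Fisher's exact test, two-sided, p = 0.17). In Double skin, which carries the same allele, the odds ratio was 1.03, and in Mek1gof, which does not, 0.983. The interval leaves open a modest share of such genes. The hypothesis arose from Hbb-b2, which proved to lie on another chromosome than Ptpn11.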
